A study of Homo sapiens with 4 samples.

How the data were processed

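Single-cell RNA-seq libraries of BT474, an established breast cancer cell line that carries the estrogen receptor and amplified HER2, were compared after 4 h of treatment. There were 4 groups with 1 library each: DMSO (the vehicle), 100 nM fulvestrant (an antagonist that also degrades the estrogen receptor), 200 nM neratinib (an irreversible inhibitor of the EGFR, HER2 and HER4 kinases) and both drugs together. Per the labels, the libraries were made with the 10x Genomics Next GEM v3 chemistry, with 3000 cells targeted per sample at 60000 reads per cell. With 1 library per group no replicate error could be had, so no gene or list was tested between groups, and cells were not used as replicates. Each drug was instead read in 2 pairs that share no library: fulvestrant alone against DMSO and both drugs against neratinib alone for fulvestrant, neratinib alone against DMSO and both drugs against fulvestrant alone for neratinib. Both drugs against DMSO made the fifth of the 5 pairs.

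The values were counts: the deposited matrix held whole-number UMI counts of 33538 genes over 27179520 unfiltered barcodes, 6794880 per library, produced by the authors with Cell Ranger 3.1.0 per the submitters' processing notes. Whether read depth was evened between the libraries when they were merged is not given in the sources used here. The library number at the end of each barcode was matched to the number that each sample title starts with, a mapping that no other label states. The processing notes name hg19, while 33456 of the gene identifiers were found in the GRCh38 annotation at hand, 33071 of them with the same symbol, so no coordinates are printed. There were 48 genes that share a symbol with another gene, and these were kept apart by identifier. The libraries held 110511222 UMIs (DMSO), 90336164 (fulvestrant), 89559704 (neratinib) and 99053622 (both drugs) over all barcodes.

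A barcode was called a cell where its UMIs reached the 99th percentile of the 3000 barcodes with most UMIs in that library divided by 10, with at least 500 genes detected and at most 20% mitochondrial UMIs. The UMI minimum came to 5178, 4826, 4864 and 5041 in the order above. Because the mitochondrial ceiling removed many more cells from the neratinib libraries than from the others, values without that ceiling are given beside the main ones. Doublets were scored with the Scrublet implementation of scanpy 1.11.5 and kept. The caller marked 15, 6, 1 and 1 cells, at most 0.409% of a library, far too few for droplet libraries of this size, so the rate of doublets is taken as not determined.

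Counts were summed over the cells of each library and divided by the library's sum to give CPM, counts scaled to the same total in every library. The kept cells held 90300352, 71663142, 33484194 and 36545639 UMIs. The log2 ratio of CPM was computed for each pair, with a 95% interval from the exact conditional binomial of 2 Poisson counts. The departure from additivity was log2 of both drugs minus log2 of fulvestrant minus log2 of neratinib plus log2 of DMSO, among 5021 genes with mean CPM of at least 20. Shares of cells have exact Clopper-Pearson 95% intervals. All of these intervals cover counting error only and say nothing about variation between cultures. The median gene shifted under total-count scaling by -0.13 for neratinib against DMSO, -0.12 for both drugs against DMSO, -0.12 for both drugs against fulvestrant, 0.00 for fulvestrant against DMSO and 0.01 for both drugs against neratinib. Small differences in the neratinib pairs should be read against that shift.

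Gene lists written from general knowledge, 21 in number, were read in every pair. They covered estrogen receptor targets, ERK output, immediate early genes, FOXO targets, sterol and lipid synthesis, MYC and ribosome biogenesis, ATF4 targets, p53 targets, glycolysis and hypoxia, S phase, G2M, receptors with their ligands, luminal factors with estrogen receptor cofactors, the TIP60 complex with BET proteins, heat shock, interferon, apoptosis, basal and mesenchymal genes, and markers of fibroblasts, immune cells and endothelial cells. A member counted as measured with mean CPM of at least 1 over the 4 libraries, which 12122 genes reached. It counted as higher or lower with a ratio of at least 1.25-fold whose interval lay off 0. The list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and that percentile is a description of these libraries, not a test. A gene can sit in more than one list.

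Genes are named by a rule. Always named were ESR1, ERBB2, PGR, GREB1, TFF1, BRD8, EGFR, ERBB3, DUSP6, CCND1 and MYC. For each drug, and for both drugs, against DMSO, the 8 highest and 8 lowest log2 ratios were named among 7301 genes with mean CPM of at least 10, without mitochondrial and ribosomal protein genes, with an interval off 0 and, for the single drugs, the same sign in the disjoint pair. In each list up to 4 members with the greatest absolute ratio were named, and for the departure the 5 highest and 5 lowest genes. Some genes that this rule selects are not reported here.

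For measures per cell, cells were thinned to 15000 UMIs and those below were left out. Cell cycle phases were scored with scanpy on the S phase and G2M lists. Clusters were drawn from the 1000 most variable of the 3614 genes that differed by no more than 0.3 in log2 between any pair of libraries, with 20 principal components, 20 neighbours, 10000 counts per cell and Leiden resolution 0.5 (leidenalg 0.10.2, igraph 0.11.9), seed 1. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.

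The cell rule, the lists, the naming rule, the pairs and the following alternatives were fixed before the data were examined: a UMI minimum multiplied by 2, no mitochondrial ceiling, called doublets left out, median-of-ratios size factors, the mean of per-cell CPM, G1 cells alone, 5% free RNA (from barcodes with 10 to 100 UMIs) subtracted, no expression minimum beyond 1 count per library, mean CPM of at least 50, unthinned cells, thinning to 7500 UMIs and Leiden resolution 1. Library totals without mitochondrial genes, the ceiling lifted together with G1 cells alone, and the ceiling lifted for phases, clusters, lists and per-cell values were added after the data were seen.

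The steps were tested on simulated Poisson counts drawn at the libraries' own depths. Of genes changed by 1 in log2, 100% passed the size rule, as did at least 99% of those changed by 0.5, and at most 0.0141% of unchanged genes passed. Between 95.1% and 95.5% of intervals held the true value. A list of 30 genes lowered by 0.3 lay at percentile 0 in every pair. For the departure, 5.87% of unchanged genes had an interval off 0. These simulations hold counting noise alone.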

Results

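The question addressed was what 4 h of estrogen receptor blockade, HER2 family kinase blockade or both do to transcription in BT474 cells, with BRD8, a bromodomain subunit of the TIP60 acetyltransferase complex named in the series title, as a gene of interest. Each group was 1 library, so no difference below has a replicate check. Ratios are log2 ratios of CPM with 95% Poisson intervals in square brackets, and values without the mitochondrial ceiling are given where they matter.

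The 13 mitochondrial transcripts took a higher share of UMIs in both neratinib libraries. The median share per cell before the ceiling was 16.2% in DMSO, 16.7% in fulvestrant, 21.1% in neratinib and 21.1% with both drugs. The ceiling of 20% therefore kept 3666 of 4290 DMSO cells (85.5% [84.4, 86.5]) and 2878 of 3494 fulvestrant cells (82.4% [81.1, 83.6]), but 1319 of 3512 neratinib cells (37.6% [36.0, 39.2]) and 1462 of 3874 cells with both drugs (37.7% [36.2, 39.3]). Median depth before the ceiling was alike, at 22587.5, 22973.5, 22232.5 and 22017 UMIs in the same order. Among the kept cells the medians were 23206, 23713, 24041 and 23344 UMIs, with 4558, 4596, 4454 and 4426.5 genes.

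With the ceiling, cells scored as G2M made up 28.8% [27.3, 30.4] of DMSO, 27.4% [25.7, 29.1] of fulvestrant, 43.4% [40.6, 46.3] of neratinib and 40.4% [37.7, 43.1] of cells with both drugs. Without it the shares were 27.0%, 25.0%, 29.8% and 27.2%, so most of that excess came with the choice of cells. S phase shares with the ceiling were 20.1%, 21.8%, 13.4% [11.6, 15.5] and 14.5% [12.6, 16.5], and without it 20.8%, 22.8%, 15.0% and 16.5%. Phase calls were not checked against a DNA content measurement, and free RNA can enter them.

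**Figure D1:**
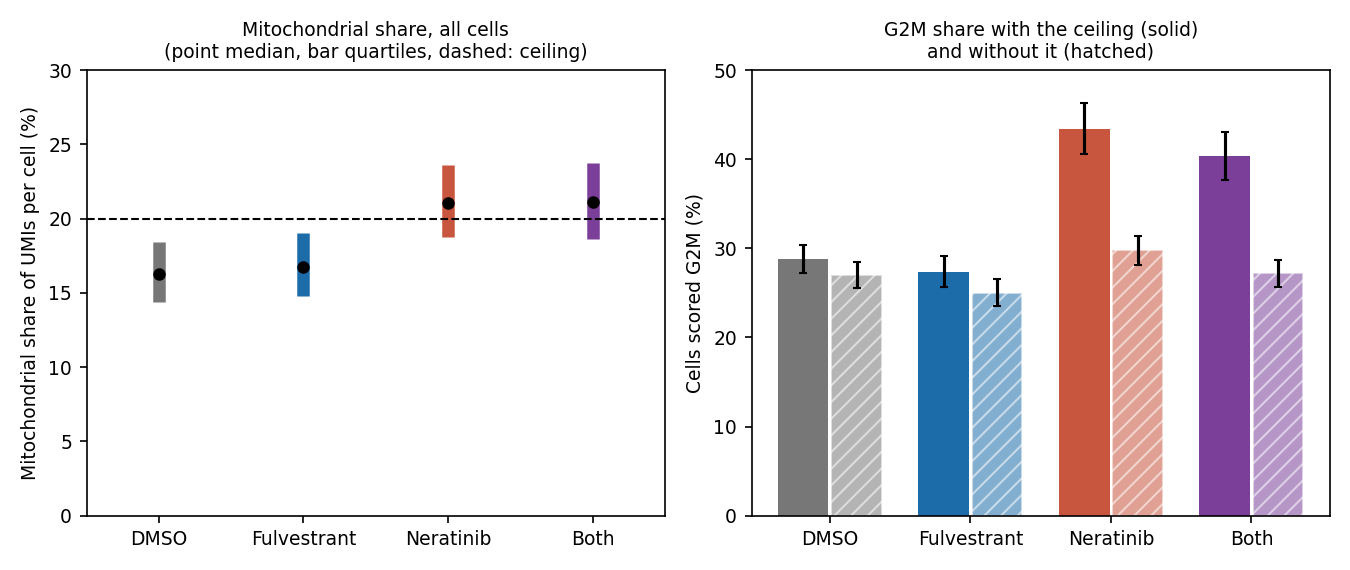
Left, mitochondrial share of UMIs per cell (percent, median with quartiles) in each library before the ceiling, drawn as a dashed line at 20%; the medians are 16.2, 16.7, 21.1 and 21.1. Right, share of cells scored as G2M (percent, 95% exact intervals) with the ceiling (solid bars) and without it (hatched bars); the neratinib library goes from 43.4 to 29.8.

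Fulvestrant against DMSO was marked by lower estrogen receptor targets. MYC, a growth-driving transcription factor, had the lowest ratio by the naming rule, at -2.26 [-2.35, -2.17], which is 4.80-fold lower (76.7 CPM in DMSO, 16.0 with fulvestrant). TSKU, a secreted proteoglycan gene, was at -1.72 [-1.81, -1.63], RARA, the retinoic acid receptor alpha, at -1.18 [-1.30, -1.06], and the EGFR ligand AREG at -0.94 [-1.01, -0.88]. The classical target genes GREB1, a receptor cofactor, and PGR, the progesterone receptor, were at -0.91 [-0.99, -0.82] and -0.80 [-0.84, -0.75], while the abundant secreted target TFF1 was only at -0.13 [-0.14, -0.12], with 2102 CPM in DMSO and 1915 with fulvestrant. ESR1, which encodes the receptor itself, was at -0.31 [-0.44, -0.19]. Other genes among the lowest were PPM1K, a mitochondrial phosphatase, at -1.26, the homeobox gene MSX2 at -1.17, MPPED2 at -1.12, STARD13, a lipid-transfer domain gene, at -1.11 and the ubiquitin ligase SIAH2 at -0.92.

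Of 36 measured estrogen receptor targets, 17 were lower and 0 higher with fulvestrant, and the list median of -0.28 lay below all 10000 matched random lists. The disjoint pair, both drugs against neratinib, again had 17 lower and 0 higher with a median of -0.35, also below every random list. There MYC was at -3.31 [-3.52, -3.11], TSKU at -2.58 [-2.76, -2.40], RARA at -1.53 [-1.76, -1.31], AREG at -1.31 [-1.50, -1.11], GREB1 at -0.86 [-0.97, -0.75] and PGR at -0.85 [-0.91, -0.79]. ESR1 was at -0.45 [-0.63, -0.27] in that pair and TFF1 at -0.11. The medians without the ceiling were -0.28 and -0.35.

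Sterol synthesis genes were among the highest with fulvestrant. INSIG1, a sterol sensor of the endoplasmic reticulum, was at 0.56 [0.48, 0.65] (23.5 CPM in DMSO, 34.7 with fulvestrant), and the synthesis enzymes MSMO1 and HMGCS1 were at 0.55 [0.48, 0.62] and 0.49 [0.45, 0.53]. In both drugs against neratinib these 3 genes were at 0.60, 0.57 and 0.47. Of 27 measured genes of sterol and lipid synthesis, 8 were higher and 0 lower against DMSO (median 0.20, above all random lists), and 6 were higher and 0 lower against neratinib (median 0.16, also above all). SLITRK6, TPRN and the xenobiotic-metabolising CYP1A1 were at 0.51, 0.42 and 0.40, with 0.28, 0.58 and 0.38 in the disjoint pair. AP001816.1, a non-coding gene, was at 0.41 [0.28, 0.54] against DMSO, but at 0.04 [-0.17, 0.24] on top of neratinib.

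Ribosome biogenesis genes were lower with fulvestrant alone. Of 35 measured members of the MYC and ribosome biogenesis list, 11 were lower and 0 higher (median -0.24), with the assembly factors NOP16 at -0.72 [-0.82, -0.62], RRS1 at -0.69 [-0.77, -0.61] and PPAN at -0.60. On top of neratinib only 3 were lower and 0 higher, with a median of -0.00 at percentile 18.1 (without the ceiling -0.03 at percentile 1.33). The apoptosis gene PMAIP1 was at -0.79 [-0.89, -0.69] and, on top of neratinib, at -1.22 [-1.38, -1.05], while its list of 16 measured genes had 1 lower and 0 higher against DMSO. IGF1R, a growth factor receptor, was at -0.62 [-0.72, -0.51] and the luminal factor GATA3 at 0.38 [0.35, 0.40] against DMSO. On top of neratinib the luminal list, with GATA3 among its 29 measured genes, had 0 higher and 4 lower. GATA3 was therefore not higher by the size rule in that pair.

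The remaining lists showed few members past the size rule with fulvestrant against DMSO. ERK output had 2 higher and 1 lower of 16 (median 0.01), immediate early genes 0 higher and 1 lower of 21 (median 0.10), FOXO targets 1 and 1 of 31, ATF4 targets 1 and 1 of 28, p53 targets 0 and 1 of 22, receptors and ligands 0 and 3 of 20, luminal factors 1 and 1 of 29, and interferon genes 0 and 1 of 14. Basal and mesenchymal genes had 1 higher and 1 lower of 7, namely the cadherin CDH2 at 0.40 [0.06, 0.74] and fibronectin FN1 at -0.39. CDH2 rests on 146 UMIs in DMSO and 153 with fulvestrant, and without the ceiling that list had 0 higher and 2 lower. Glycolysis, S phase, G2M, TIP60 and heat shock lists had 0 in either direction. Some medians still lay at the edge of the random lists. S phase was at 0.06 (percentile 100) and G2M at -0.04 (percentile 0). On top of neratinib they were at 0.11 and -0.14, with the same percentiles. Glycolysis was at -0.05 (percentile 0.3) and -0.06 (percentile 0.09) in these pairs. Immediate early genes and FOXO targets lay at percentiles 100 and 99.98 against DMSO. On top of neratinib they lay at 59.3 and 84.6, and without the ceiling at 99.99 and 81.6. Against DMSO, ERBB2, which encodes HER2, was at 0.07 [0.05, 0.08], BRD8 at -0.06 [-0.15, 0.03], EGFR at 0.05 and ERBB3 at 0.05.

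Neratinib against DMSO was marked by a lower read-out of growth factor signalling. The transcription factor genes FOS and EGR1, induced within minutes of receptor signalling, were at -4.49 [-4.89, -4.13] and -3.95 [-4.21, -3.70], which is 22.5-fold and 15.5-fold lower (40.4 to 1.79 CPM and 61.0 to 3.94 CPM). DUSP6, an ERK phosphatase induced by ERK, was at -3.14 [-3.58, -2.73], PHLDA2 at -3.12 [-3.32, -2.93], CCND1, which encodes cyclin D1, at -2.69 [-2.76, -2.62], the kinase gene PLK2 at -2.31 [-2.47, -2.16] and the ERK phosphatase DUSP4 at -1.84 [-1.90, -1.77]. TLCD1, IER2 and PPAN followed at -1.89, -1.87 and -1.86. Of 16 measured ERK output genes 14 were lower and 1 higher (median -1.62), and of 21 immediate early genes 14 were lower and 1 higher (median -0.62), with NR4A1, a nuclear receptor, at -1.36 [-1.54, -1.19]. Both medians lay below all random lists, and without the ceiling the ERK median was -1.50.

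In the disjoint pair, both drugs against fulvestrant, ERK output had 15 lower and 1 higher (median -1.48) and immediate early genes 14 lower and 1 higher (median -0.55). FOS was at -4.65, EGR1 at -4.19, PHLDA2 at -3.06, DUSP6 at -3.66 [-4.19, -3.17] and CCND1 at -2.92. PLK2, TLCD1, IER2 and PPAN were at -2.30, -1.77, -1.77 and -1.40.

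FOXO targets, genes held down while PI3K and AKT signal, were higher with neratinib. Of 31 measured targets 23 were higher and 2 lower against DMSO (median 0.71, above all random lists), and 22 higher and 2 lower against fulvestrant (median 0.74). HBP1, a transcriptional repressor, was at 2.24 [2.17, 2.31] (26.7 to 126 CPM), the PI3K inhibitor gene PIK3IP1 at 2.19 [2.04, 2.34], YPEL3 at 2.14 [2.07, 2.21] and the insulin receptor INSR at 1.38 [1.21, 1.54]. TNFSF10, which encodes the death ligand TRAIL, had the highest ratio of all named genes at 2.68 [2.53, 2.82], 6.40-fold. CREBRF, a regulator of metabolism, was at 2.37 [2.26, 2.48], the autophagy receptor CALCOCO1 at 2.32 [2.18, 2.45], KLHL24, a ubiquitin ligase adaptor, at 2.31 [2.23, 2.39] and CCDC28A at 2.02 [1.84, 2.21]. Against fulvestrant the same genes, from HBP1 to CCDC28A without INSR, were at 2.13, 2.00, 1.83, 2.26, 2.31, 2.29, 2.37 and 1.94.

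BRD8 was 2.78-fold higher with neratinib, at 24.0 CPM in DMSO, 23.1 with fulvestrant, 66.8 with neratinib and 69.0 with both drugs. Its ratio was 1.48 [1.39, 1.56] against DMSO and 1.58 [1.49, 1.67] in the disjoint pair, and without the ceiling 1.34 and 1.40. Fulvestrant on top of neratinib left it at 0.05 [-0.04, 0.13]. Most of the TIP60 and BET list stayed near DMSO: of 24 measured genes, BRD8 among them, 3 were higher and 1 lower, with MBTD1, another TIP60 subunit, at 1.16 [1.04, 1.27], EPC2, a scaffold of the complex, at 0.49 [0.33, 0.66] and HEXIM1, a transcription elongation inhibitor, at -0.70 [-0.84, -0.57]. That list's median was -0.03 and turned to 0.11 with median-of-ratios scaling. Without the ceiling 3 were higher and 5 lower.

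Receptor genes were higher or lower with neratinib depending on the gene. ERBB3, the kinase-poor partner of HER2, was at 1.04 [0.99, 1.10] against DMSO (61.6 to 127 CPM) and 1.01 [0.95, 1.07] against fulvestrant, and GRB7, an adaptor gene beside ERBB2, at 1.43 [1.40, 1.46]. EGFR was at -0.67 [-0.89, -0.46] and AREG at -1.72 [-1.83, -1.60]. ERBB2 was at -0.10 [-0.12, -0.08] but at 0.04 with median-of-ratios scaling, so its direction depends on the scaling. Of 20 measured receptors and ligands 7 were higher and 6 lower.

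Estrogen receptor targets were mostly lower under neratinib, with a few exceptions. GREB1 was at 0.33 [0.24, 0.41], just past the size rule and under it without the ceiling (0.27), and the kinase SGK3 at 0.69 [0.59, 0.78], and PGR had a ratio of 0.22 [0.17, 0.27], under the size rule. ESR1, the receptor gene and no member of that list, was at 0.29 [0.15, 0.43], also under the size rule. Under the main settings MYC was at -0.36 [-0.43, -0.29] and TFF1 at -0.22 [-0.23, -0.21] against DMSO. The list as a whole had 2 higher and 20 lower against DMSO (median -0.36, percentile 0.09) and 2 higher and 19 lower against fulvestrant (median -0.37). It includes FOS and CCND1, which are also ERK responsive. Median-of-ratios scaling gave 3 higher and 14 lower.

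The ribosome biogenesis, glycolysis and ATF4 lists had lower medians with neratinib in both pairs, and the sterol list was not lower than other genes. MYC and ribosome biogenesis had 27 lower and 0 higher of 35 (median -0.68), with RRS1 at -1.78 [-1.93, -1.63], NOP16 at -1.28 [-1.44, -1.12] and PNO1 at -1.18. On top of fulvestrant 22 were lower and 1 higher (median -0.38). ATF4 targets, the amino acid stress genes, had 16 lower and 0 higher of 28 (median -0.34), with TRIB3 at -0.93 [-1.02, -0.85], the transporter SLC7A1 at -0.92 and CEBPB at -0.80 [-0.85, -0.75]; with median-of-ratios scaling 11 were lower and 4 higher. On top of fulvestrant ATF4 targets had 12 lower and 3 higher (median -0.24, percentile 3.57), and without the ceiling 16 lower and 3 higher (median -0.38, percentile 0.22). Glycolysis and hypoxia had 13 lower and 1 higher of 26 (median -0.35), with the vessel growth factor VEGFA at -1.26 [-1.43, -1.09], the oxygen sensor EGLN3 at -0.98 [-1.12, -0.85] and NDRG1 at 0.71 [0.60, 0.83]. On top of fulvestrant glycolysis had 12 lower and 1 higher (median -0.32, percentile 0.39). Median-of-ratios scaling gave 10 lower and 1 higher glycolysis genes against DMSO (median -0.22), and 9 lower and 1 higher on top of fulvestrant (median -0.20). For ATF4 targets on top of fulvestrant it gave 8 lower and 4 higher (median -0.12). Sterol and lipid genes had 10 lower and 0 higher (median -0.15, percentile 36.5), with the desaturase FADS1 at -0.85 [-0.94, -0.77] and SQLE, a sterol enzyme, at -0.51; median-of-ratios scaling gave 5 lower and 2 higher (median -0.02).

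Luminal factors had 14 lower and 4 higher of 29 with neratinib (median -0.29, percentile 0.21). The keratin KRT19 was at -0.85 [-0.87, -0.84], SPDEF at -0.73 and GATA3 at -0.70 [-0.75, -0.66]. Median-of-ratios scaling gave 7 lower and 8 higher, with a median of -0.15. Against fulvestrant the list had 13 lower and 3 higher (median -0.25, percentile 0.815). Against DMSO, S phase had 12 lower and 2 higher of 42 (median -0.12, percentile 61.5, without the ceiling 13.7). It was led by the nucleotide reductase RRM2 at -1.20 [-1.33, -1.08] and cyclin CCNE2 at -1.13 [-1.27, -0.99]. Median-of-ratios scaling gave 9 lower and 4 higher. G2M had 37 higher and 2 lower of 54 (median 0.49), led by the phosphatase CDC25C at 1.38 [1.23, 1.54], but 12 higher and 9 lower without the ceiling (median 0.11, still at percentile 100 of the random lists, CDC25C 1.04), so the size of this difference depends on the choice of cells.

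Of 22 measured p53 targets 3 were higher and 10 lower with neratinib (median -0.10, percentile 69.3). The ubiquitin ligase MDM2 was at -0.62 [-0.74, -0.49] and the death gene BBC3 at 0.56 [0.45, 0.66]. Apoptosis genes had 3 higher and 6 lower of 16 (median -0.14, percentile 49.4), with BCL2, a survival gene, at -0.68 [-0.86, -0.50]. Neither list was therefore lower than other genes. Heat shock had 1 higher and 5 lower of 16, with the chaperone HSPA4 at -0.60, but 2 higher and 2 lower with median-of-ratios scaling and 0 higher and 8 lower without the ceiling. Median-of-ratios scaling also gave 3 higher and 4 lower apoptosis genes and 2 and 2 basal genes. Interferon genes had 3 higher and 1 lower of 14, but 2 and 2 without the ceiling. Basal and mesenchymal genes had 0 higher and 2 lower of 7, with the integrin ITGA6 at -0.64 under the main scaling. Heat shock, interferon and basal medians lay at percentiles 14.1, 62.6 and 54.8, and heat shock at 1.6 without the ceiling.

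**Figure D2:**
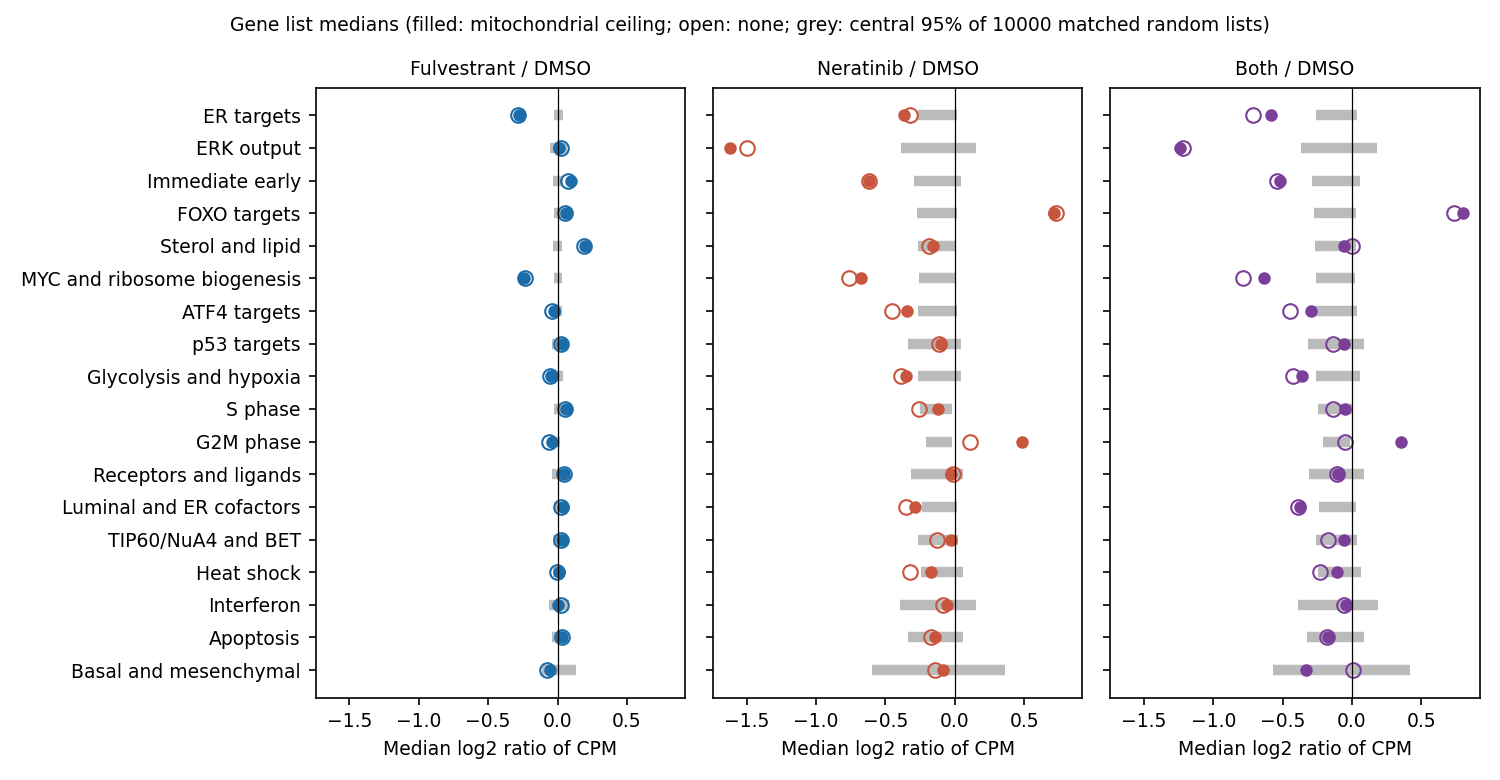
Median log2 ratio of each of 18 gene lists for fulvestrant, neratinib and both drugs against DMSO (filled, with the ceiling; open, without it), with grey bars for the central 95% of 10000 matched random lists. ERK output lies at -1.62 and FOXO targets at 0.71 with neratinib, and the G2M median of 0.49 moves to 0.11 without the ceiling.

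MYC, CCND1, AREG and TSKU were lower with both drugs than with either drug alone. MYC was at -3.67 [-3.87, -3.48] against DMSO, 12.7-fold lower (76.7 to 6.02 CPM), and CCND1 at -3.27 [-3.35, -3.18], 9.62-fold lower (318 to 33.1 CPM). Genes of the neratinib response stayed near their level with neratinib alone, with FOS at -4.57 [-4.96, -4.21], EGR1 at -3.96 [-4.21, -3.72], PHLDA2 at -3.08 [-3.26, -2.90] and PLK2 at -2.30 [-2.44, -2.15]. DUSP6 was at -3.75 [-4.28, -3.27], AREG at -3.02 [-3.19, -2.86] and TSKU at -2.83. PGR and GREB1, whose ratios with the single drugs had opposite signs, were at -0.63 and -0.53, TFF1 was at -0.33 [-0.35, -0.32] and ESR1 at -0.16. Of 36 estrogen receptor targets 29 were lower and 0 higher (median -0.59, without the ceiling -0.71, below all random lists), against 17 lower with fulvestrant alone and 20 with neratinib alone. Fulvestrant on top of neratinib put CCND1 at -0.58 [-0.68, -0.47].

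The genes that were higher with both drugs were those of neratinib. CREBRF was at 2.57 [2.46, 2.67], KLHL24 at 2.48 [2.41, 2.56], TNFSF10 at 2.48 [2.33, 2.63], HBP1 at 2.28 [2.21, 2.35], PIK3IP1 at 2.25 [2.10, 2.39], CALCOCO1 at 2.25, CCDC28A at 2.09 and YPEL3 at 2.03. BRD8 was at 1.52 [1.44, 1.61] (without the ceiling 1.33), ERBB3 at 1.06, GRB7 at 1.40, MBTD1 at 1.28 and the cyclin CCNG2 at 1.45 [1.41, 1.49]. EGFR was at -0.61 and ERBB2 at -0.13 [-0.15, -0.11]. FOXO targets had 22 higher and 2 lower (median 0.80), ERK output 14 lower and 0 higher (median -1.24) and immediate early genes 14 lower and 1 higher (median -0.52).

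Ribosome biogenesis had 29 lower and 0 higher with both drugs (median -0.63), with RRS1 at -2.29 [-2.46, -2.12]. Sterol and lipid genes held both drugs' directions, with INSIG1 at 0.88 [0.78, 0.97] and FADS1 at -0.92, and 5 were higher and 4 lower. Luminal factors had 15 lower and 4 higher, with KRT19 at -1.32 [-1.34, -1.31] and the secretory factor XBP1 at -1.06 [-1.10, -1.03]. ATF4 targets had 12 lower and 3 higher, although DDIT4, an inhibitor of mTOR, was at 0.90 [0.79, 1.00]. Glycolysis had 15 lower and 1 higher, with EGLN3 at -1.43. PMAIP1 was at -1.29 in an apoptosis list with 2 higher and 7 lower. Counts higher and lower were 5 and 10 for p53 targets, 3 and 9 for S phase, 7 and 7 for receptors, 5 and 2 for TIP60, 1 and 5 for heat shock, 3 and 2 for interferon, and 1 and 3 for basal genes. With median-of-ratios scaling they were 7 and 7 for S phase, 2 and 2 for heat shock, 1 and 1 for basal genes, 5 and 0 for TIP60, and 6 and 1 for sterol and lipid genes, so the lower tilt of the first 3 depends on the scaling. Luminal factors then had 11 lower and 6 higher (median -0.26), and they lay at percentile 0 under the main scaling. Under the main scaling the p53, S phase, heat shock and apoptosis medians lay well within the random lists. Their percentiles were 72.2, 86.0, 37.3 and 31.1. Without the ceiling the TIP60 list had 3 higher and 5 lower, so its tilt depends on the choice of cells, and interferon genes had 4 and 4. G2M had 28 higher and 3 lower (median 0.35), but 7 higher and 11 lower (median -0.05, percentile 98.9) without the ceiling.

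**Figure D3:**
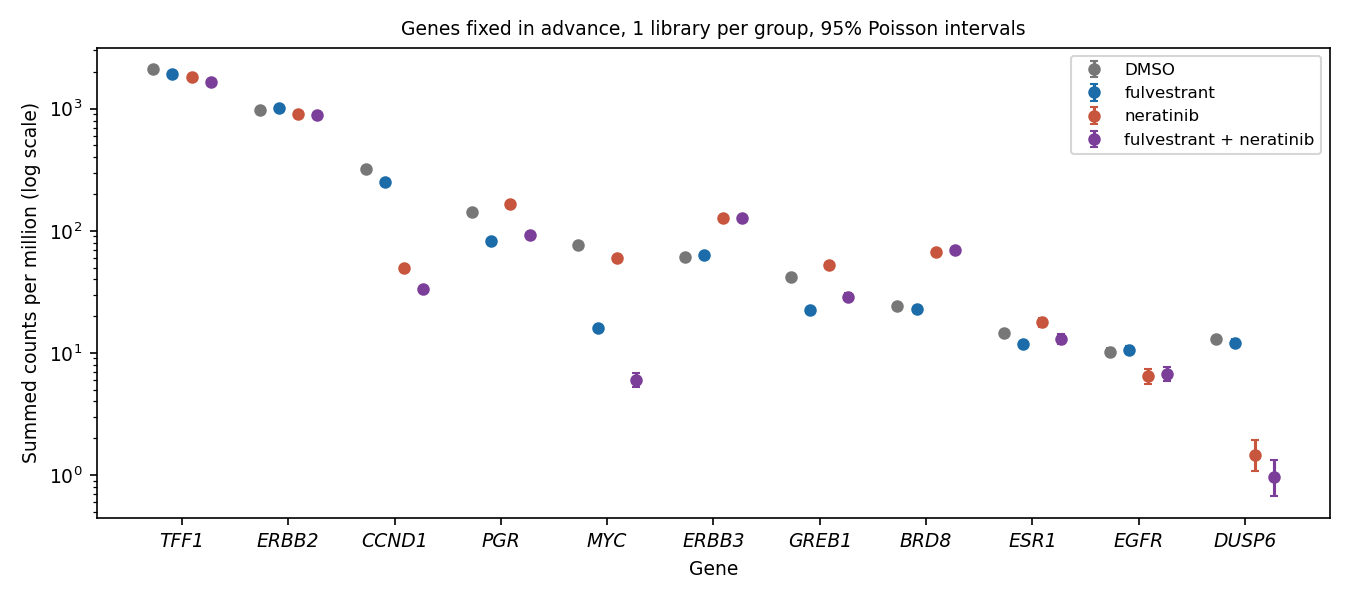
CPM of the 11 always-named genes in each library on a log scale, with 95% Poisson intervals. BRD8 goes from 24.0 in DMSO to 66.8 with neratinib, while MYC goes from 76.7 to 6.02 with both drugs.

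Departures from additivity, the level with both drugs against the sum of the single log2 effects, were lowest for MYC at -1.05 [-1.27, -0.83] and TSKU at -0.86 [-1.06, -0.66], so the fulvestrant ratio of both genes was lower on top of neratinib than without it. DKK1, a WNT inhibitor, was at -0.64 [-0.77, -0.52] (without the ceiling -0.42), C6orf141 at -0.52 and the kinetochore gene SPC25 at -0.45 [-0.63, -0.26] (without the ceiling -0.26). The highest were nucleolar genes, the helicase DDX21 at 0.53 [0.43, 0.63] and NOC3L, RPF2, WDR43 and NOM1 at 0.50, 0.48, 0.46 and 0.43. Without the ceiling RPF2 was at 0.34 and NOM1 at 0.27. Ribosome biogenesis had 9 members higher than additive and 1 lower (median 0.24, above all random lists), estrogen receptor targets 0 higher and 5 lower (median -0.07, percentile 0.10) and ERK output 1 higher and 0 lower (median -0.17, without the ceiling -0.08). BRD8 was near additive at 0.11 [-0.02, 0.23] and CCND1 at -0.23 [-0.34, -0.11].

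Across 7301 genes, the ratios of the neratinib pairs had a Pearson r of 0.95 and a Spearman correlation of 0.94, and those of the fulvestrant pairs an r of 0.50 and a Spearman correlation of 0.23. In G1 cells alone the fulvestrant values were 0.286 and 0.113, and the neratinib values 0.907 and 0.884. Genes such as FOS, EGR1 and TNFSF10 for neratinib and MYC and TSKU for fulvestrant lay at the same end in both pairs. The naming rule by rank asked for the same sign in both pairs, so their shared sign carries no weight here. The fulvestrant ratios had standard deviations of only 0.106 and 0.134, against 0.404 and 0.402 for neratinib. Counting error therefore weighs more on the fulvestrant correlation, by an amount that was not measured. These correlations are across genes, which are not independent replicates.

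**Figure D4:**
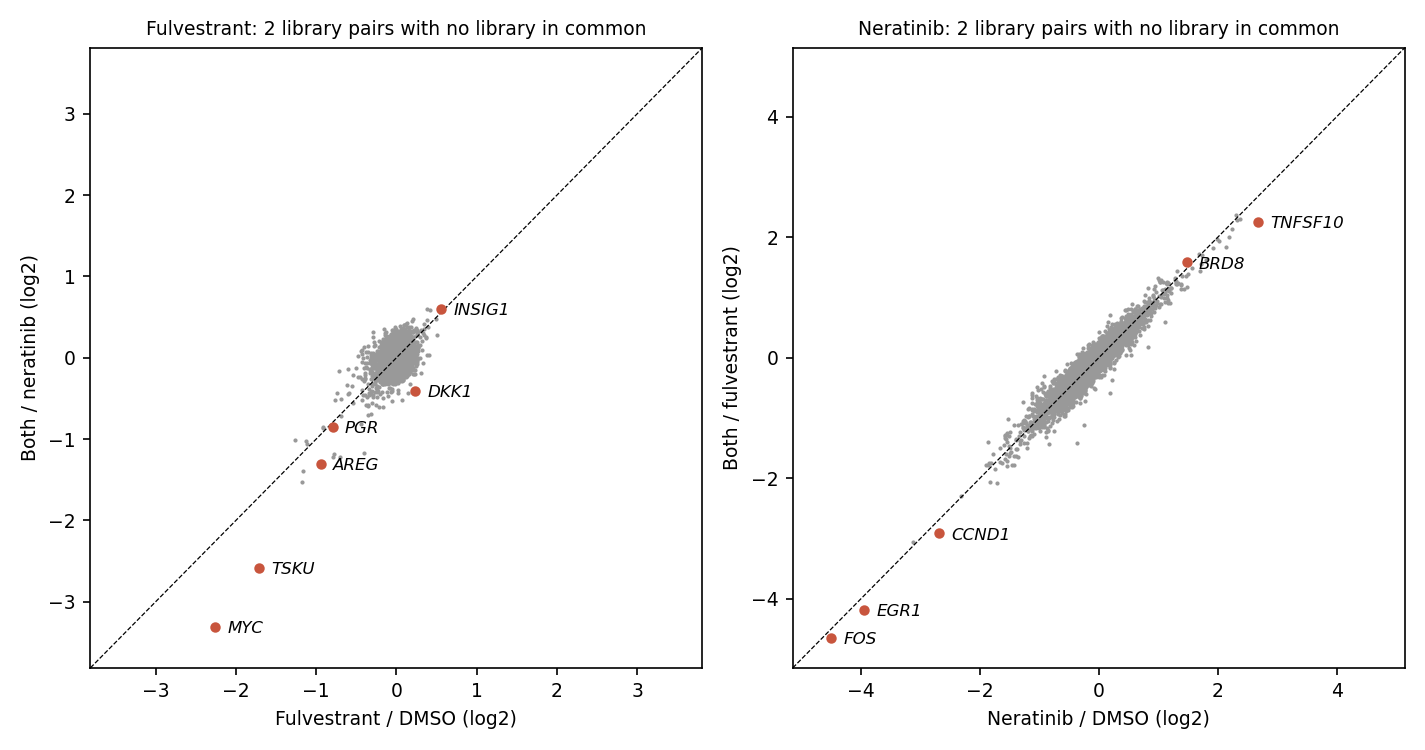
Log2 ratios of 7301 genes in the disjoint pairs for fulvestrant (left) and neratinib (right). MYC lies at -2.26 and -3.31 on the left, and BRD8 at 1.48 and 1.58 on the right.

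Summed over each list, the ERK and FOXO differences with neratinib were seen in most cells, while estrogen receptor targets overlapped widely between libraries. Such sums give most weight to abundant members. Of the estrogen receptor targets, TFF1 had 2102 CPM in DMSO and a ratio of only -0.13 with fulvestrant. Of the ERK output genes, CCND1 had 318 CPM in DMSO and a ratio of -2.69 with neratinib. The wide overlap may therefore not hold for less abundant estrogen receptor targets, which were not read singly per cell. At 15000 UMIs per cell, the ERK output genes had a median of 11 UMIs in DMSO, 11 with fulvestrant, 3 with neratinib and 2 with both drugs, and only 1.09% [0.583, 1.86] of neratinib cells and 0.528% [0.213, 1.09] of cells with both drugs lay above the DMSO median, against 49.7% of DMSO cells. FOXO targets had medians of 20, 21, 32 and 32 UMIs, with 93.7% of neratinib cells above the DMSO median. Estrogen receptor targets had medians of 61, 51, 46 and 38, with 49.8% of DMSO cells, 32.6% [30.9, 34.5] of fulvestrant cells, 26.1% [23.7, 28.7] of neratinib cells and 15.7% [13.8, 17.8] of cells with both drugs above the DMSO median.

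Clustering on genes that differed little between the libraries gave 6 clusters at Leiden resolution 0.5, each with cells of every library. That choice of genes favours such mixing by construction, so the mixing says nothing about the drugs. At resolution 1 the G1 cells parted by neratinib: a cluster led by BASP1, a membrane signalling protein, held 34.0% of DMSO, 33.7% of fulvestrant, 7.65% of neratinib cells and 5.28% of cells with both drugs, and one led by TNFSF10 and CALCOCO1 held 1.41%, 1.62%, 20.6% and 24.0%. The shares that follow are at resolution 0.5. A cluster led by S phase genes held 31.8% of DMSO, 33.1% of fulvestrant, 29.0% of neratinib cells and 30.1% of cells with both drugs, and a G2M cluster held 16.9%, 15.8%, 21.8% and 19.5%. The cluster with most cells, mostly in G1, held 37.1%, 36.9%, 29.6% and 30.9%. In a separate clustering without the ceiling, a cluster with like G2M leading genes held 16.8%, 14.8%, 15.8% and 13.3%. The cluster with most cells there, also mostly in G1, held 38.3%, 38.0%, 40.6% and 42.1%. The larger G2M and smaller G1 shares of the neratinib libraries therefore depend on the choice of cells. A cluster led by NMU, a neuropeptide, and the chaperone HSP90B1 held 8.64%, 9.10%, 17.1% and 15.9%. In the clustering without the ceiling, a cluster also led by NMU held 8.07%, 8.89%, 10.3% and 9.63%. A hypoxia-like cluster led by NDRG1 and VEGFA had 223 cells, 96.4% of them in G1, and held 3.48%, 3.1%, 1.09% and 0.906%. A cluster with like leading genes in the clustering without the ceiling was another set of 1024 cells, 66.4% of them in G1, so their shares are not set side by side. One led by CYP1A1 and the stress factors DDIT3 and ATF3 held 2.04%, 2.00%, 1.43% and 2.72%. In the clustering without the ceiling, a cluster with like leading genes held 2.00%, 1.94%, 1.27% and 1.35%. The larger share with both drugs therefore depends on the choice of cells.

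No cluster had a marker of fibroblasts, immune cells, endothelial cells or basal cells among its 10 leading genes, and none had a luminal marker either. Leading genes were drawn from those with mean CPM of at least 1. That left out most fibroblast and endothelial markers, all immune ones and all basal ones but VIM. The leading genes therefore cannot tell cell types apart here. Of 8 fibroblast markers 1 was measured, COL1A1, a collagen, at 11.2, 12.3, 9.77 and 9.36 CPM. Of 6 endothelial markers 1 was measured, VWF, a clotting factor, at 2.09, 2.36, 1.79 and 1.70 CPM, and of 9 immune markers 0 were.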

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

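Of the tests in this part, only the one on genes beside BRD8 was written before its result was seen; all other tests were chosen after the results were seen, and the bound of the test on nuclear transcripts was rewritten after its value was known.

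BRD8 was higher with neratinib in both pairs, which made it a pattern to weigh. A shift in cell cycle phases is argued against by the smallest ratio within any phase, 1.17, against 1.34 over all cells without the ceiling. A choice of cells by the mitochondrial ceiling is argued against by the ratio of 1.34 without it, against 1.48 with it. Reads of a measured neighbouring gene are argued against because the highest measured neighbour within 10 kb, KIF20A on the opposite strand, reached 0.20 in both pairs. NME5, a neighbour on the same strand with a mean of 0.08 CPM, was below the measured level and is not covered. An effect of the drug on BRD8 may remain as a hypothesis, open and untested, since each group had 1 library and differences between cultures were not tested.

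The mitochondrial ceiling left out 62.4% [60.8, 64.0] of neratinib cells and 62.3% [60.7, 63.8] of cells with both drugs, against 14.5% of DMSO cells, a difference between groups far outside counting error. A damaged part of the cells is argued against because the lower quartile of the share shifted by at least 0.872 of the shift of the median, so the whole distribution lay higher. Cell cycle phases are argued against because medians among G1 cells still differed by at least 4.73 percentage points, against 4.44 over all cells. A loss of nuclear transcripts with mitochondrial ones left as they were cannot be told apart from a rise of mitochondrial transcripts: the ratios of the 13 mitochondrial genes ranged over 0.34 in neratinib against DMSO but over 0.22 in the disjoint pair, against 0.20 in the wider fulvestrant pair, so the pairs did not decide alike. A small range would also follow from an equal rise of all 13 genes. Median mitochondrial UMIs per cell before the ceiling were 3755.5 in DMSO, 3930.5 in fulvestrant, 4840.5 in neratinib and 4779 with both drugs. Median other UMIs were 18913, 19135.5, 17442.5 and 17337. UMIs per cell also depend on the sequencing of each single library, so these values do not decide. A biological effect of neratinib on the mitochondrial share stays open and untested.

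The departures from additivity were weighed for MYC and for ribosome biogenesis genes. For MYC, at 6.02 CPM with both drugs against 12.5 CPM from the log2 effects, the scale cannot be told apart from an interaction: the linear sum was -0.914 CPM, so a level 6.93 CPM above it decides nothing. For ribosome biogenesis the scale stays open too, since 91.4% of members, 32 of 35, lay above the linear sum, but in 31 of the 35 that sum lies below the log2 one, which fixes much of the outcome. Cell cycle phases are argued against there because the smallest median departure within a phase was 0.19, against 0.22 over all cells without the ceiling. An interaction of the drugs on ribosome biogenesis stays open and untested, with no replicate behind the 4 libraries.

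Among the named genes, 14 had fulvestrant ratios of opposite sign on top of neratinib and without it with both intervals off 0, and these differences were not tested. The ratio was higher on top of neratinib for DDX21 (0.10 against -0.43), NOM1 (0.21 against -0.22), RPF2 (0.19 against -0.28), RRP1B (0.23 against -0.13), SLC7A1 (0.31 against -0.14), HSPA4 (0.10 against -0.08) and HSP90AB1 (0.10 against -0.05). It was lower on top of neratinib for DKK1 (-0.41 against 0.23), TNFSF10 (-0.20 against 0.22), YPEL3 (-0.12 against 0.19), GRB7 (-0.033 against 0.25), VPS72 (-0.15 against 0.09), HMGB2 (-0.16 against 0.03) and ERBB2 (-0.037 against 0.066). Without the ceiling the ratio on top of neratinib was 0.04 for NOM1, 0.03 for RPF2, 0.10 for SLC7A1, -0.25 for DKK1, -0.06 for VPS72, -0.021 for GRB7 and -0.068 for ERBB2.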

How the results depend on the processing

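The settings without the mitochondrial ceiling for lists, phases, clusters and per-cell values, those with totals that leave out mitochondrial genes, and the ceiling lifted with G1 cells alone were chosen after seeing the data; the others were planned. Of 326 values that answer a comparison under an alternative, 266 stayed within their interval or count limit, 60 moved and 0 reversed. Of 1030 other values 833 stayed, 195 moved and 2 reversed. Only list medians, departures, correlations and named-gene ratios could be labelled reversed. Counts and shares could only stay or move, so for them the lack of reversals says nothing. The G2M list with both drugs, at 28 higher and 3 lower, came to 7 and 11 without the ceiling and counts as moved. The intervals of medians and correlations were centred on the main value after first looks. The sign of named-gene log2 ratios held in 766 of 770 cases. DUSP6 with fulvestrant against DMSO, -0.09 with an interval that holds 0, came to 0.0048 in G1 cells and 0.0084 in G1 cells without the ceiling. The other 2 were ERBB2 with neratinib against DMSO, from -0.10 to 0.037 with median-of-ratios size factors and to 0.054 without the ceiling and without mitochondrial genes in the total. No paired analysis was possible because each group had 1 library.

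For estrogen receptor targets, fulvestrant against DMSO (-0.28) came to -0.20 at mean CPM of at least 50 and -0.21 in G1 cells without the ceiling, and both drugs against neratinib (-0.35) to -0.54 in G1 cells and -0.19 at CPM 50. Both drugs against DMSO (-0.59) came to -0.71 without the ceiling, -0.47 with median-of-ratios size factors and -0.71 in G1 cells without the ceiling. Neratinib against DMSO (-0.36) came to -0.23 with median-of-ratios, -0.29 in G1 cells, -0.29 at CPM 50, -0.24 without the ceiling and mitochondrial totals and -0.30 in G1 cells without the ceiling. The departure (-0.07) came to -0.14 in G1 cells and -0.0047 at CPM 50. ERK output with neratinib against DMSO (-1.62) came to -1.37 in G1 cells without the ceiling, against fulvestrant (-1.48) to -1.19 in G1 cells and -2.06 at CPM 50, and with both drugs against DMSO (-1.24) to -2.08 at CPM 50. For these values the cause was not tested.

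At CPM 50 fewer members are measured by construction: lower estrogen receptor targets went from 17 to 4, 17 to 5, 29 to 10 and 20 to 5 (fulvestrant against DMSO, both against neratinib, both against DMSO, neratinib against DMSO), lower ERK genes from 14, 15 and 14 to 3 in each pair with neratinib, and higher FOXO targets from 23, 22 and 22 to 9. The G2M list had 37 higher members with neratinib with the ceiling and 12 without.

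The fulvestrant correlation (0.504) was 0.575 without the ceiling, 0.476 with per-cell CPM, 0.286 in G1 cells, 0.483 with free RNA subtracted, 0.0658 without an expression minimum, 0.453 at CPM 50, 0.575 without the ceiling and mitochondrial totals and 0.406 in G1 cells without the ceiling; its Spearman value ranged from 0.0955 without an expression minimum to 0.290 without the ceiling. The neratinib correlation (0.954) was 0.968, 0.949, 0.907, 0.950, 0.643, 0.968, 0.968 and 0.946 in that order. Without a minimum, genes with few counts enter by construction; otherwise the cause was not tested.

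Lifting the ceiling gave 3512 neratinib cells and 3874 with both drugs, by construction. G2M shares (28.8%, 27.4%, 43.4%, 40.4%) were 26.2%, 24.7%, 39.7% and 35.0% unthinned and 27.0%, 25.0%, 29.8% and 27.2% without the ceiling. S phase shares were 17.6% in DMSO and 18.7% in fulvestrant at 7500 UMIs, and with both drugs 16.7% unthinned and 16.5% without the ceiling. At 7500 UMIs, 35.0% of fulvestrant cells lay above the DMSO median of ERK output, against 39.96% of DMSO cells, where ties lower both shares. Leiden resolution 1 gave 13 clusters, among them G1 clusters that differ in share between libraries with and without neratinib. The cause of these was not tested. Depth limits genes near 1 CPM most, where a ratio rests on few UMIs.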

Other observations

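Without the ceiling all 13 mitochondrial genes were higher with neratinib against DMSO, from 0.10 for MT-ATP8 to 0.44 for MT-CYB, and against fulvestrant, from 0.16 for MT-ND6 to 0.38 for MT-CYB. Counts of the 95 ribosomal protein genes took 20.3%, 20.1%, 21.8% and 21.6% of kept UMIs in DMSO, fulvestrant, neratinib and both drugs. TSKU, the other gene with a low departure besides MYC, was at 8.02 CPM with both drugs, against 8.35 CPM from the sum of single effects on the linear scale, a comparison chosen after the departure was seen.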
